A study of Tachycineta bicolor and Sialia sialis and Hirundo rustica with 121 samples.

How the data were processed

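The series measured gene expression by RNA sequencing of total RNA from the ventromedial telencephalon of 121 birds, 61 females and 60 males of 10 species, with stranded mRNA libraries. The deposited table held raw counts of reads per gene for 10672 genes, with 1 column per bird, and the values were whole numbers. Per the submitters' processing notes the tools were Trimmomatic 0.36, fastp 0.20.1, Bowtie2 2.4.4, SAMtools 1.10 and featureCounts of Subread 2.02z, and the genome reference and annotation are not given in the sources used here, beyond a gene column headed as zebra finch protein identifiers. Genes carry symbols, and 911 entries without a symbol were tested and counted but not named. Total counts per bird ran from 4526413 to 7549296, and all 121 columns were matched to a labelled bird. The aggression scores and plasma testosterone of the series were not analysed here.

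Birds were grouped by species, sex and nesting strategy from the labels alone. Open cup and facultative nesters formed 1 class of less obligate nesters, except in a comparison of the 3 families with an open cup partner and the 2 with a facultative one. Bird numbers repeat across species and sexes, and the expression profiles gave no sign that equal numbers pair birds, so all fits were unpaired. The tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined, apart from the additions named below.

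Computations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and ape 5.8.1, and figures used Python 3.11.15 with matplotlib 3.10.9. The 2 species of each family were compared with edgeR's quasi-likelihood test on TMM-scaled counts after filterByExpr, with sex as a covariate and only those species in the fit. Sex and its interaction with obligate nesting were tested in the same way over all birds, with species as a covariate. Nesting strategy across families was tested with limma on the 10 species means of log2 CPM (prior count 2), with family as a block and 4 residual degrees of freedom, since strategy is a property of the species. The type of partner was tested on the same means with 3 residual degrees of freedom. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and 0.05 was the threshold for an adjusted p. Genes called in 1 direction in all 5 families and the mean Spearman correlation between families were set against all 16 assignments of the label within families. Shares of variance are sequential sums of squares of log2 CPM, for which no p was computed.

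Lists of genes were compared with all other genes by limma's camera with a preset correlation of 0.01, over 22 lists and, for nesting strategy, 132 tests, namely each list in each family and over the species means. The 22 lists cover sex steroid signalling, the stress axis, neuropeptides and their receptors, monoamine signalling, GABA and glutamate receptors, immediate early genes, the circadian clock, thyroid hormone signalling, oxidative phosphorylation, cytosolic ribosomal proteins, heat shock and protein folding, Z-linked genes, Z genes with a W copy, and markers of oligodendrocytes, astrocytes, microglia, endothelial and mural cells, blood cells, choroid plexus and ependyma, excitatory neurons, inhibitory and striatal neurons, and hypothalamus. Lists share members: another list holds 10 of 66 measured Z-linked genes, 6 of 25 inhibitory and striatal markers, 4 of 14 stress axis genes, 3 of 23 sex steroid genes and 3 of 41 oxidative phosphorylation genes, and none of the 7 blood cell markers.

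Within a family, the genes named are the 5 highest and 5 lowest by log2 fold change among genes with a symbol past the threshold, with a mean of at least 5 CPM in both species and no overlap between the birds of the 2 species. Across families they are the 12 higher and 12 lower genes with the largest smallest change over the families, and the 5 higher and 5 lower with the smallest p over species means. By sex they are the 10 highest and 10 lowest past the threshold with at least 5 CPM in 1 sex, and for interactions the 3 with the smallest p in each direction. Up to 4 members of a called list and 18 genes named beforehand were added, of which 13 were present and 5 had no entry under that symbol. Genes without a symbol that the rule took were counted and not named. Some genes that the rule takes are not reported here.

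The tests were checked on simulated data, in which 200 genes were changed in negative binomial counts with the means and dispersions of these birds, or in normal draws with the residual spread of the species means. In the 5 families the share of genes recovered was 46.3% to 85.1% at 1.5-fold, 77.6% to 98.5% at 2-fold and at least 98.5% at 4-fold. It was 94.0% for sex and 80.6% for the interaction at 1.5-fold. On the 10 species means it was 0% at 1.5-fold, 16.4% at 2-fold and 65.2% at 4-fold, and for the type of partner 0% at each. False calls made up 2.75% to 7.33% of the calls in the families, 1.01% for sex, 4.66% for the interaction and 5.26% on the species means. The simulated counts gave all species the same mean and effect, so the interaction was not checked against spread of the sex difference between species.

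The alternatives were DESeq2, RLE factors, library size only, quantile normalization, no filter or a minimum mean of 1 CPM, minimum changes, each sex alone, each family or species left out or taken alone, bird number as a block, a joint fit of all species, edgeR with birds as replicates, voom with species as a random effect, phylogenetic generalized least squares, limma on species differences, an estimated correlation in camera, and fry. Chosen after seeing the data were fits without doubted libraries, without mitochondrial genes, without genes that differ by sex, on the birds of the block without the block, lists without Z-linked members, and the count over species fitted alone. A library was doubted when its median correlation with its own group was under 0.9, which held for 4, or when its CHD1W level went against its label, which held for 2. No 2 libraries were copies of each other among 306 pairs compared within groups. No library was left out of the values reported first.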

Results

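Gene expression was measured by RNA sequencing in the ventromedial telencephalon, a forebrain region, of 121 adult birds from 10 songbird species. Each of 5 families contributed 1 species that nests only in cavities, called an obligate cavity nester, and 1 species with a less strict habit. The obligate nesters were Tree Swallow (Hirundinidae, 13 birds), Prothonotary Warbler (Parulidae), Eurasian Tree Sparrow (Passeridae), House Wren (Troglodytidae) and Eastern Bluebird (Turdidae), each of the last 4 with 12 birds. Their partners were Barn Swallow, Yellow Warbler and American Robin, which build open cups, and House Sparrow and Carolina Wren, which use cavities facultatively, each with 12 birds. Every species had 6 females and 6 males except Tree Swallow, which had 7 females. The birds were taken while territories and nests were being established and before eggs were laid. The table held 10672 genes, of which 911 carried no gene symbol, and the total count per bird ran from 4526413 to 7549296. Levels are given as CPM, the counts scaled to the size of the library. The labels number the birds separately within species and sex, so that p-values describe the spread between birds, and for nesting strategy the spread between species.

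Family and species accounted for most of the variance of expression. Over genes, the median share of the variance in log2 CPM was 40.5% for family, 21.3% for species within family and 0.126% for sex, and 28.8% was left between birds of the same species and sex. The part that the 5 families shared as a difference between obligate and less obligate nesters had a median of 2.24%. This part is 1 of the 5 degrees of freedom of species within family, so it takes some variance even where the families share no difference. All 121 libraries correlated best with the mean of their own labelled species. A few stood apart within it: Eastern Bluebird male 12, Barn Swallow females 3 and 4 and House Sparrow female 3 had median correlations of 0.860, 0.896, 0.893 and 0.881 with the other birds of their species and sex. CHD1W, the copy of the chromatin remodeller CHD1 on the female-limited W chromosome, went against the label in the libraries labelled Carolina Wren female 1 (8.29 CPM) and Carolina Wren male 3 (63.8 CPM). The other Carolina Wren females had at least 52.0 CPM and the other males between 7.42 and 14.3 CPM. All 6 libraries stayed in the comparisons under their labels, and the counts of genes and lists by family, across families, by strategy and by sex were also computed without them.

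**Figure D1:**
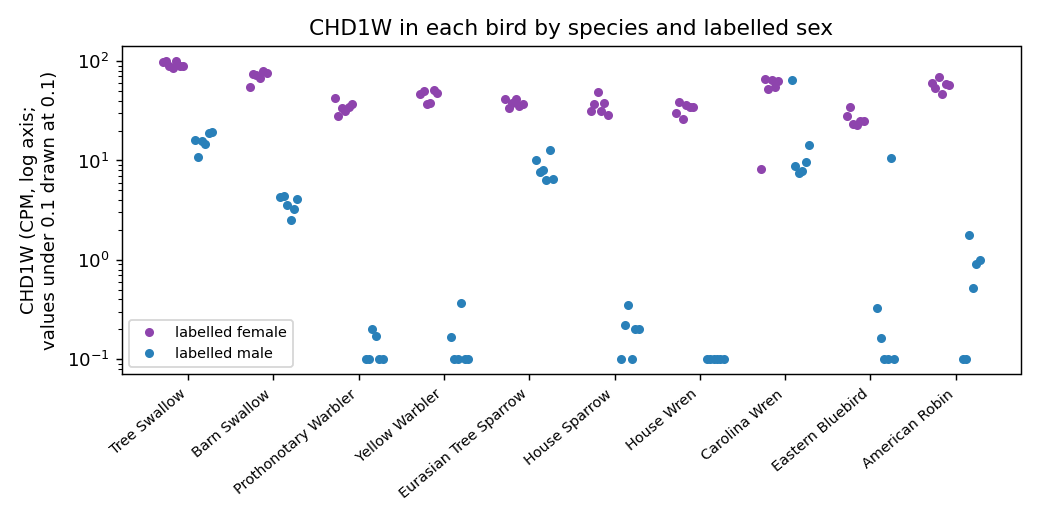
CHD1W in CPM (log axis, values under 0.1 drawn at 0.1) in each of the 121 birds, by species and by the sex in the label. Labelled females lie above labelled males of their species except in Carolina Wren, where the library labelled female 1 is at 8.29 and the library labelled male 3 at 63.8.

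The first comparison asked which genes differed between the 2 species of each family. Each fold change between species includes any difference in how reads of the 2 species matched the reference, which is not given in the sources used here. In Hirundinidae, Tree Swallows had 327 ± 55.5 CPM of TRIM37 (SD, n = 13), a ubiquitin ligase, against 11.5 ± 6.15 in Barn Swallows (n = 12), a log2 difference of 4.78 ± 0.27 (SE). FTH1, the ferritin heavy chain that stores iron, stood at 2157 ± 351 CPM against 137 ± 35.9 (log2 3.93). The adhesion receptor ADGRV1 was also higher (log2 4.04). The neuronal adhesion protein ASTN1 (log2 -4.29), the membrane protein TMEM181 (-3.96) and the kinesin light chain KLC4 (-3.82) were lower in Tree Swallows. Of 10524 genes tested, 5721 differed (edgeR, adjusted p under 0.05), 2719 higher and 3002 lower in Tree Swallows, and 1542 of them by at least 2-fold.

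In Parulidae, MAP2, which organises microtubules in dendrites, was at 326 ± 106 CPM in Prothonotary Warblers and 7.66 ± 2.93 CPM in Yellow Warblers (SD, n = 12 each), a log2 difference of 5.57 ± 0.20 (SE). The Golgi protein TRIP11 was higher as well (log2 3.90). The synaptic adhesion protein TENM4 was at 23.5 ± 5.79 against 211 ± 35.6 CPM (log2 -2.99), and the axon guidance receptor ROBO1 (-3.60), GGACT (-3.63) and CLEC16A (-2.88) were lower too. Of 10500 genes, 5815 differed, 2947 higher and 2868 lower in Prothonotary Warblers, and 1258 by at least 2-fold. Scaling by library size alone put 33.1% of the differing genes higher in place of 50.7%, with a median shift of all genes of -0.17 on the log2 scale.

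In Passeridae, EIF2S1, a subunit of the initiation factor that delivers the first tRNA, was at 203 ± 14.1 CPM in Eurasian Tree Sparrows and 16.3 ± 3.53 CPM in House Sparrows (SD, n = 12 each; log2 3.81 ± 0.11 SE). The receptor phosphatase PTPRE (log2 4.06), the histone deubiquitinase MYSM1 (3.71) and the mitochondrial outer membrane protein CISD1 (3.69) were higher. The cohesin regulator PDS5B was at 18.6 ± 2.73 against 274 ± 62.3 CPM (log2 -3.68), and the helicase WRN (-3.29), the receptor GPR179 (-2.88) and the potassium channel KCNH7 (-2.66) were lower. Of 10495 genes, 5143 differed, 2543 higher and 2600 lower in Eurasian Tree Sparrows, and 1306 by at least 2-fold. Scaling by library size alone put 30.9% of the differing genes higher in place of 49.4%, with a median shift of -0.20.

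In Troglodytidae, CABIN1, an inhibitor of the phosphatase calcineurin, was at 184 ± 15.9 CPM in House Wrens and 12.3 ± 2.37 CPM in Carolina Wrens (SD, n = 12 each; log2 3.88 ± 0.09 SE). PCNX2 (log2 3.28), the topoisomerase TOP3A (3.05) and the actin regulator PHACTR3 (3.04) were higher. Calnexin, the endoplasmic reticulum chaperone encoded by CANX, was at 37.3 ± 4.30 against 655 ± 67.0 CPM (log2 -4.15), and the phosphatase subunit PPP2R5D (-4.21) and EFR3A (-3.58), which anchors a lipid kinase at the plasma membrane, were lower. Of 10522 genes, 5983 differed, 3225 higher and 2758 lower in House Wrens, and 1236 by at least 2-fold. The library labelled Carolina Wren female 1 and that labelled male 3 entered under their labels, with sex as a covariate.

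In Turdidae, EFR3A went the other way: it was at 549 ± 147 CPM in Eastern Bluebirds and 10.7 ± 3.12 CPM in American Robins (SD, n = 12 each; log2 5.65 ± 0.18 SE). The receptor phosphatase PTPRS (log2 5.17), the co-chaperone DNAJA1 (5.06) and NADSYN1, which makes NAD (3.99), were higher. CFAP46, a protein of motile cilia (log2 -3.84), the collagen COL7A1 (-3.64) and C1D (-3.63), a cofactor of the RNA exosome, were lower. All 7 measured blood cell markers were lower in Eastern Bluebirds, with a median log2 of -1.57, and 7 of 9 microglia markers were lower and 2 higher, with a median of -0.99. Neither list stood out from other genes (camera adjusted p = 0.339 and 0.414, and 0.986 for both with an estimated correlation). Of 10565 genes, 5943 differed, 3013 higher and 2930 lower in Eastern Bluebirds, and 1892 by at least 2-fold. Males alone gave 3627 differing genes.

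Among the genes named in each family, the largest fold change was that of a mitochondrially encoded gene. These genes code for subunits of the respiratory chain and lie on 1 small genome, and within a pair of species they went in both directions. ND2 was at 12404 ± 1471 CPM in Tree Swallows and 46.2 ± 63.4 CPM in Barn Swallows (log2 8.07) while ATP6 was at 88.7 ± 137 against 22036 ± 2753 CPM (log2 -8.08), with ND5 (5.56) following ND2 and ND4 (-7.18) following ATP6. In Parulidae, ATP6 (log2 11.76), COX1 (10.59) and ND5 (7.92) were higher and ND1 (-3.03) lower in Prothonotary Warblers. COX1 was higher (4.43) and ATP6 lower (-10.40) in Eurasian Tree Sparrows. ATP6 was higher (4.44) and ND4 (-11.29) and ND1 (-9.62) lower in House Wrens, and ND6 was higher (7.23) and ND3 (-6.08) and ND4 (-4.42) lower in Eastern Bluebirds. COX1 in Yellow Warblers was at 49.3 ± 102 CPM (SD, n = 12) with a median of 4.70, and ND3 in Eastern Bluebirds at 20.7 ± 38.5 CPM (n = 12) with a median of 2.39, so that for both genes the medians of the 2 species lie further apart than the means. Summed over the 12 genes present, the mitochondrial share of counts had a species mean between 6.12% in Eastern Bluebirds and 20.2% in Prothonotary Warblers. The library labelled House Sparrow female 3 lay far from its species in several of these genes, as in COX3 with 78272 CPM where the other 11 House Sparrows had 3.90 to 20.3 CPM.

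**Figure D2:**
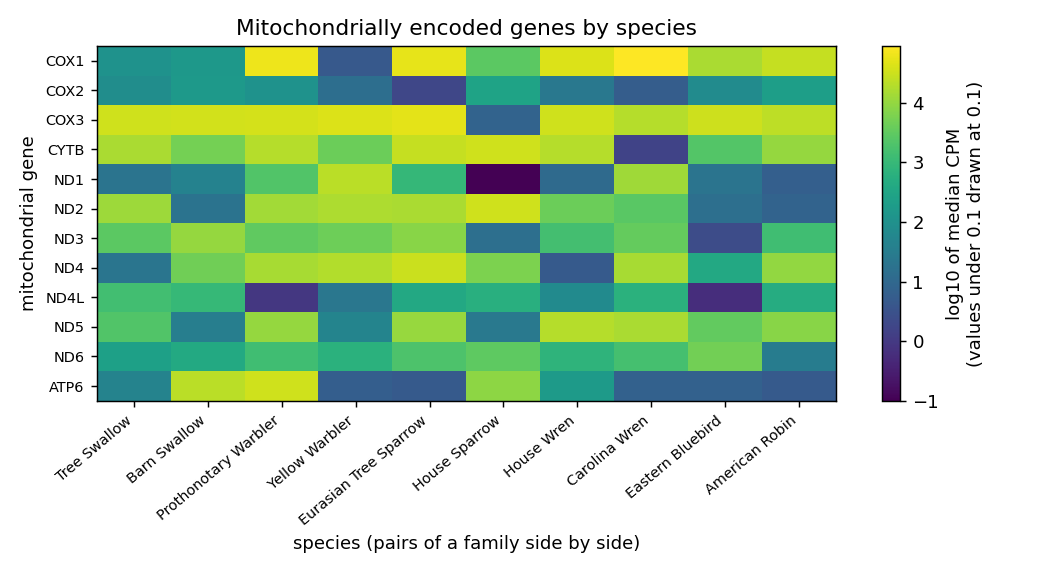
Median over birds of the CPM of 12 mitochondrially encoded genes (log10 colour scale, values under 0.1 drawn at 0.1) in the 10 species, with the 2 species of a family side by side. Neighbouring columns differ in both directions, as for ND2 (log2 8.07 in Hirundinidae) and ATP6 (-8.08 in the same family).

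The next comparison asked whether the families shared a difference between obligate and less obligate nesters. Of 10284 genes tested in all 5 families, 988 differed in every one, and 54 of these did so in a single direction, 33 higher and 21 lower in obligate nesters. BCHE, the butyrylcholinesterase that hydrolyses choline esters, was higher by a log2 of 0.62 to 1.48 (mean 1.01). LDB3, a cytoskeletal adaptor with PDZ and LIM domains (0.60 to 2.52), and, by their means, SLC7A6OS (0.88), the phosphatase PTPDC1 (1.05), MPHOSPH10 and TAF1B of ribosome production (0.78 and 0.90), the co-chaperone TTC4 (1.03) and DYNC1LI2, a dynein subunit (0.64), were higher in all 5. So were DNAAF9 (1.34), the transcription factor SOX5 (0.86), NT5C2, which dephosphorylates nucleotides (0.63), and WDR73 (0.56).

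The genes lower in obligate nesters in all 5 families included CLCC1, a chloride channel protein of the endoplasmic reticulum, with log2 values between -1.45 and -0.84 (mean -1.25). MOGAT1, an acyltransferase of triglyceride synthesis (mean -1.18), the thioredoxin reductase TXNRD3 (-0.89), the Notch glucosyltransferase POGLUT1 (-1.19), EML6 (-1.19), CDADC1 (-1.06), the postsynaptic protein LRRC7 (-0.75) and GTDC1 (-0.96) were lower throughout. The methionine salvage enzyme ADI1 (-0.71), the ribosomal protein RPS12 (-0.85), the phosphatase subunit PPP2R2D (-1.75) and the mitochondrial carrier SLC25A24 (-0.84) completed the 12 with the widest margin. CLCC1 was also lower by -1.25 ± 0.16 (SE) between the means of 5 obligate and 5 less obligate species, with an unadjusted limma p of 0.000118 and an adjusted p of 0.952.

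**Figure D3:**
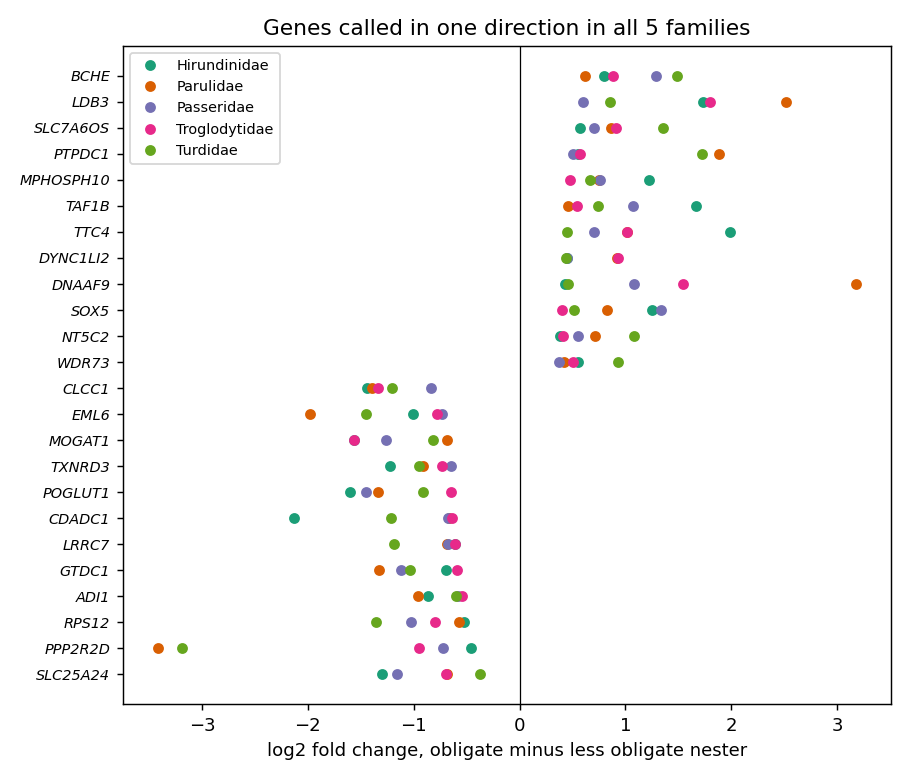
Log2 fold changes (obligate minus less obligate nester) in the 5 families for 24 genes that differed in a single direction in every family. Each point is 1 family, and CLCC1 ranges from -1.45 to -0.84 where BCHE ranges from 0.62 to 1.48.

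The number of such genes was set against the 15 other ways of exchanging the 2 labels within families. These gave 50 to 78 genes with a median of 62, and 15 of the 16 assignments gave at least 54. If the directions of the 988 genes were random, 61.8 would fall in 1 direction, and independent calls in the 5 families would give 30.4. Fold changes did not rank alike between families: across genes, which are not independent replicates, the mean Spearman rho over 10 pairs of families was -0.00105 (range -0.0149 to 0.0123), against -0.00594 to 0.00455 for the other assignments.

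**Figure D4:**
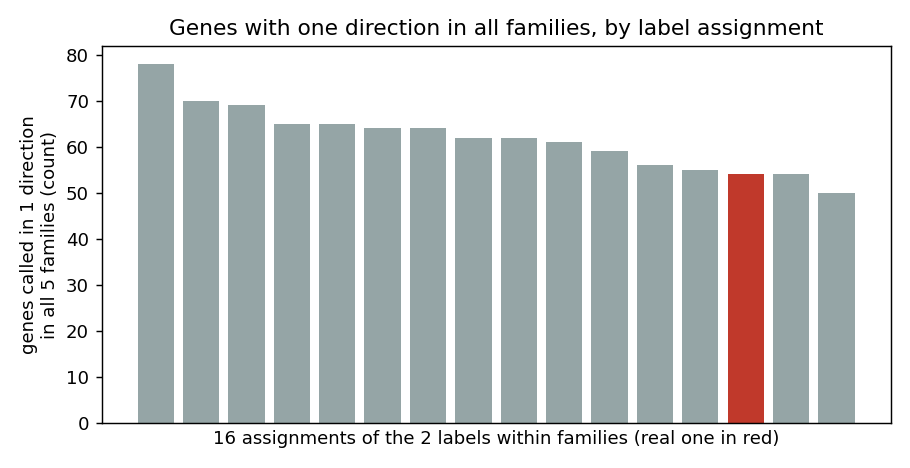
Number of genes called in 1 direction in all 5 families (bar height, axis from 0) for the 16 assignments of the 2 nesting labels within families, sorted by height. The real assignment, in red, gives 54 genes, and the others give 50 to 78.

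With the 10 species means as the units, limma called 0 of 10648 genes for nesting strategy, and the lowest adjusted p was 0.952. At an unadjusted p under 0.05 there were 482 genes, 258 of them higher in obligate nesters, where 532 are expected by chance. The smallest p-values belonged to BCHE, SLC7A6OS (0.88 ± 0.17 SE) and 3 genes without a symbol among those higher, and to CLCC1, TXNRD3 (-0.91), POGLUT1 (-1.17), MOGAT1 (-1.15) and EML6 (-1.18) among those lower, each in 5 of 5 families. Other treatments of the same question gave other counts. A phylogenetic regression on the species means called 6 genes, namely BCHE (adjusted p = 0.0370), CLCC1 (0.0252), MOGAT1 (0.0358), POGLUT1 (0.0317), TXNRD3 (0.0317) and 1 without a symbol. It used an assumed tree in place of the family block, which leaves more residual degrees of freedom, and gave these genes the same log2 differences. A voom fit with species as a random effect called 320, and edgeR with birds as the units called 5119.

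The difference between the species of a pair depended on the family for 9529 of 10648 genes (edgeR, adjusted p under 0.05). The partner was an open cup nester in 3 families and a facultative cavity nester in 2, and limma called 0 genes for a dependence on that difference, with 447 at an unadjusted p under 0.05. After 1 gene without a symbol, the genes with the smallest p-values among positive differences were BSG, a membrane glycoprotein (difference of log2 values, open cup minus facultative, 4.29 ± 0.57 SE), and PCCA, a propionyl-CoA carboxylase subunit (2.58), and among negative ones the kinase CDKL2 (-2.62) and the ubiquitin ligases RNF149 (-2.07) and MUL1 (-2.39). Without Troglodytidae, which leaves Passeridae as the only family with a facultative partner, it called 3 genes, ADCY5 (difference -6.99), the mitochondrially encoded COX3 (-11.53) and KCNAB2 (8.06), chosen after their values were seen.

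Of 18 genes named beforehand for steroid, peptide and monoamine signalling, 13 were measured. NR3C1, the glucocorticoid receptor, was lower in the obligate nester in 5 of 5 families and past the threshold in 2 of them. It was at 21.0 ± 2.53 CPM in House Wrens against 46.1 ± 8.60 in Carolina Wrens (SD, n = 12 each; log2 -1.14 ± 0.09 SE, adjusted p = 1.65e-11) and at 31.0 ± 8.03 in Eastern Bluebirds against 56.6 ± 12.9 in American Robins (log2 -0.88 ± 0.14, adjusted p = 3.90e-06). Over species means its log2 difference was -0.54 ± 0.21, with an adjusted p of 0.952 over all genes and 0.474 adjusted over the list alone.

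Aromatase, the oestrogen-making enzyme encoded by CYP19A1, was higher in Tree Swallows (log2 0.75) and House Wrens (0.76) and lower in Eastern Bluebirds (-0.91). The oestrogen receptors ESR1 (1.07 and 0.63) and ESR2 (0.78 and 0.59) were higher in Eurasian Tree Sparrows and House Wrens, and ESR2 was lower in Tree Swallows (-0.45). The vasotocin receptor AVPR1A was higher in Eurasian Tree Sparrows (1.09) and lower in Prothonotary Warblers (-0.68), and the serotonin receptor HTR1A was higher in House Wrens (0.86) and lower in Prothonotary Warblers (-0.39) and Eastern Bluebirds (-1.20). VIPR1 was higher in House Wrens (0.41) and lower in Eastern Bluebirds (8.33 against 16.5 CPM), the dopamine receptor DRD2 was higher in House Wrens (0.89), CRH in Eurasian Tree Sparrows (0.61) and SRD5A2, a steroid reductase, in Prothonotary Warblers (0.57). Neither TH nor DRD1 passed the threshold in any family. With edgeR p-values adjusted over the list alone, 20 of the combinations of 13 genes and 5 families passed. ESR2 in Tree Swallows (adjusted p = 0.106) and HTR1A in Prothonotary Warblers (0.0710) did not. Among all genes tested, adjusted over all genes, 49.0% to 56.9% passed in each family, so such calls do not set these genes apart. None of the 13 passed over species means.

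Gene lists fixed beforehand were compared with all other genes by limma's camera. In Passeridae, 19 of 41 nuclear genes of oxidative phosphorylation were higher and 3 lower in Eurasian Tree Sparrows, with a median log2 of 0.25 (adjusted p = 0.0471, and adjusted p = 0.986 with an estimated correlation), led by ATP5PF (4.53 ± 0.94 SE), COX6A1 (3.44), NDUFB8 (2.85) and NDUFB9 (2.35), all subunits of respiratory complexes. Of the same 41 genes, 4 were higher and 11 lower in Prothonotary Warblers, against 17 and 5 in Tree Swallows, 17 and 7 in House Wrens and 15 and 6 in Eastern Bluebirds, with adjusted p from 0.414 to 0.935. In Passeridae 7 of 17 endothelial and mural markers were higher and 0 lower (median 0.23, adjusted p = 0.414), and 5 of 11 astrocyte markers were higher and 1 lower (median 0.23, adjusted p = 0.863), with 0.986 for both with an estimated correlation. Over the species means, 32 of the 41 were above 0, with a median of 0.14 and an adjusted p of 0.0437 (0.986 with an estimated correlation), and 0 passed the test one by one. No other list and comparison of the 132 passed, and neither of these calls held with an estimated correlation. Fry, which asks whether a list's genes move on balance 1 way without comparing them with other genes, passed 40 of the 132.

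For the other lists, the number of genes above 0 over species means and the median log2 difference were as follows. Among signalling lists, sex steroid signalling had 9 of 23 (-0.08), the stress axis 6 of 14 (-0.14), neuropeptides and their receptors 16 of 30 (0.02), monoamine signalling 11 of 27 (-0.08), GABA and glutamate receptors 10 of 31 (-0.08), immediate early genes 4 of 24 (-0.11), the circadian clock 8 of 18 (-0.02) and thyroid hormone signalling 2 of 8 (-0.44). Heat shock and protein folding had 12 of 29 (-0.05), cytosolic ribosomal proteins 22 of 61 (-0.07), Z-linked genes 36 of 66 (0.06) and Z genes with a W copy 11 of 17 (0.25). Among cell type markers, oligodendrocytes had 5 of 11 (-0.05), astrocytes 6 of 11 (0.05), microglia 2 of 9 (-0.22), endothelial and mural cells 10 of 17 (0.01), blood cells 0 of 7 (-0.29), choroid plexus and ependyma 4 of 9 (-0.12), excitatory neurons 6 of 11 (0.01), inhibitory and striatal neurons 13 of 25 (0.02) and hypothalamus 3 of 7 (-0.18).

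Females and males of all species were then compared by label. ACAA2, a mitochondrial thiolase, stood at 39.4 CPM in females and 82.7 CPM in males, a log2 difference (male minus female) of 1.06 ± 0.05 (SE), and was higher in males in 10 of 10 species. AGXT2, a mitochondrial aminotransferase (1.07), TRIM14 (1.05), CZH9orf64 (1.04), RCL1 of ribosome production (1.02), the sorting nexin SNX24 (1.01), TTC33 (1.01), SLF1 of DNA repair (1.01), TAF1C (1.01) and CCDC171 (0.99) also were higher in males in 10 of 10 species. CHD1W was at 49.3 CPM in females and 4.96 CPM in males (-4.08 ± 0.24). The oestrogen receptor ESR2 was at 10.1 and 7.13 CPM (-0.48 ± 0.10), lower in males in every species. GREB1, an oestrogen-induced gene in other tissues (-0.43), the kinesin KIF18A (-0.48), MACIR (-0.41), the erythrocyte membrane protein EPB42 (-0.42), the haemoglobin HBAD (-0.40), CSAD, which makes taurine (-0.38), and ENHO (-0.35) were lower in males too.

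In all, 555 of 10648 genes differed by sex (edgeR, adjusted p under 0.05), 442 higher in males and 113 higher in females, and 376 had the same sign in 10 of 10 species. The median log2 difference was 0.68 for the genes higher in males and -0.24 for those higher in females. Of the genes higher in males, 405 lay between 0.3 and 1.1. A difference of at least 2-fold was seen for 28 genes, and 17 of the 18 of these that were higher in females had no symbol. DCAF12 was called lower in males (-0.83 ± 0.21) but was higher in males in 4 of 10 species. By species its log2 difference was -4.06 in Prothonotary Warblers and -3.80 in Yellow Warblers, but 0.46 in Tree Swallows and 1.23 in Barn Swallows. Of the genes named beforehand, CYP19A1 (0.60 ± 0.11, from 18.8 to 28.0 CPM) and HTR1A (0.45 ± 0.10) were higher in males, each in 10 of 10 species. Males carry 2 copies of the Z chromosome and females 1, but genes outside the fixed lists were not assigned to chromosomes. For such genes named as higher in males, an effect of the second Z copy cannot be told apart from other sex differences.

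Each species was also tested alone, with 352 genes in Tree Swallow, 228 in Barn Swallow, 290 in Prothonotary Warbler, 283 in Yellow Warbler, 290 in Eurasian Tree Sparrow, 190 in House Sparrow, 496 in House Wren, 193 in Eastern Bluebird and 211 in American Robin. Carolina Wren gave 0 in edgeR, with 584 at an unadjusted p under 0.05, and 250 without the libraries labelled female 1 and male 3. No gene was therefore called in 1 direction in all 10 species under the labels, while 93 were without the 6 libraries named above, 89 of them higher in males. DESeq2 and limma were run over all species together, where they called 578 and 444.

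Of 66 measured genes of the Z chromosome, of which males carry 2 copies and females 1, 61 were higher in males and 1, DCAF12, was lower. The list had a median log2 of 0.58 (camera adjusted p = 3.01e-129, and 9.37e-15 with an estimated correlation). RAD1 (0.98), DNAJA1 (0.97), CCNH (0.91) and APTX (0.91) led it. Of 17 Z genes with a W copy, 9 were higher in males and 0 lower (median 0.22, adjusted p = 7.46e-15, and 5.98e-08 with an estimated correlation), among them BTF3 (0.88), RPL17 (0.87), CHD1 (0.64) and HNRNPK (0.52). The median of the Z-linked genes per species lay between 0.39 in Carolina Wren, with the 2 libraries that go against their labels included, and 0.73 in Prothonotary Warbler. Without these 2 libraries Carolina Wren was at 0.55, and House Wren was lowest at 0.47.

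**Figure D5:**
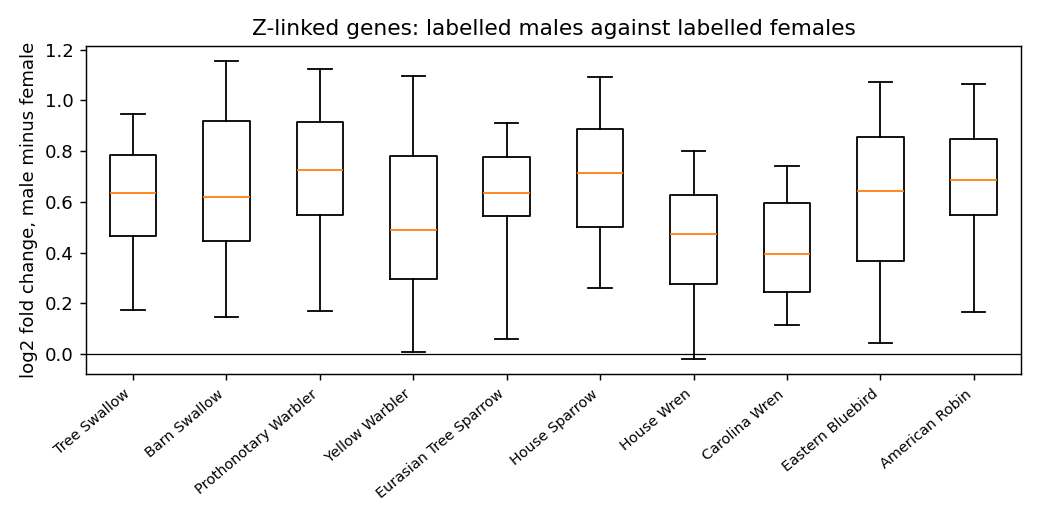
Log2 fold change (labelled males minus labelled females) of the measured Z-linked genes in each species, as boxes from the first to the third quartile with a line at the median and whiskers from the 5th to the 95th percentile. Medians lie between 0.39 in Carolina Wren, which includes the libraries labelled female 1 and male 3, and 0.73 in Prothonotary Warbler. Without these libraries, which is not drawn, Carolina Wren is at 0.55 and House Wren is lowest at 0.47.

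Sex steroid signalling was higher in males (5 of 23 genes higher and 1 lower, median 0.03, adjusted p = 0.00533), but 3 of the 5, HSD17B4 (0.89), PRLR (0.75) and GHR (0.69), are also in the Z-linked list. Without these 3 its adjusted p was 0.840, and with an estimated correlation it was 0.113 for the whole list. All 7 blood cell markers were below 0 (median -0.33, adjusted p = 0.0182), 2 of them past the threshold over all genes and 7 adjusted over the list alone. That call was lost with an estimated correlation (adjusted p = 0.581) and without the 6 libraries (0.0586). With an estimated correlation only the Z-linked list and the Z genes with a W copy kept their calls, while fry passed 6 of 22 lists.

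None of the remaining lists passed, and their medians by sex (male minus female) were small. They were -0.02 for the stress axis, 0.00 for neuropeptides and their receptors, 0.02 for monoamine signalling, 0.01 for GABA and glutamate receptors, -0.06 for immediate early genes, 0.01 for the circadian clock, 0.02 for thyroid hormone signalling, -0.04 for oxidative phosphorylation, -0.06 for cytosolic ribosomal proteins and 0.02 for heat shock and protein folding. Among cell type markers they were -0.02 for oligodendrocytes, -0.01 for astrocytes, -0.19 for microglia, -0.12 for endothelial and mural cells, 0.04 for choroid plexus and ependyma, -0.03 for excitatory neurons, 0.01 for inhibitory and striatal neurons and -0.10 for hypothalamus. The median and the direction of the test differed in sign for GABA and glutamate receptors, thyroid hormone signalling, oxidative phosphorylation, astrocytes and excitatory neurons.

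The last comparison asked whether the sex difference itself depended on nesting strategy. In all, 6 genes were called for this dependence (edgeR), and 680 had an unadjusted p under 0.05. Of the 6, 2 were among 5 genes expressed almost only in females in most species, a set that asked for a female mean of at least 5 CPM. Another, without a symbol, had male means at or near 0 in most species but 10.4 CPM in House Wren males. Without House Wren its adjusted p was 0.999 (edgeR). A further entry without a symbol had a lower mean in males than in females in every species. Leaving out the libraries labelled Carolina Wren female 1 and male 3 gave 11 genes, of which 5 were among the 6, and limma on the 10 species differences called 0, with 510 at an unadjusted p under 0.05. DESeq2 called 10.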

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

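The tests chosen after the result was seen were the counts of mitochondrial genes far apart in both directions or moving as a whole, the counts of female-limited genes in 2 Carolina Wren libraries, the use of the planned estimated correlation to weigh oxidative phosphorylation and its fit without doubted libraries, and the other assignments for the concordant genes and the correlation between families. So was the rule that too few ribosomal protein genes decide nothing where the share of all genes would give under 3, and that the mitochondrial count alone decides nothing; the predictions set earlier had read the first as against and the second as for differences in matching the reference.

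Mitochondrially encoded genes differed between the species of a family with an SD of their log2 fold changes between 4.32 and 6.06, and 37 to 73 genes per family in all lay 20-fold apart. A shift of all mitochondrial transcripts together is argued against, since the number of families in which all 12 genes went 1 way with a small spread was 0, and ATP6 (log2 -8.08) and ND2 (8.07) parted in Hirundinidae. Gene by gene differences in how well reads of a species match the reference cannot be told apart from differences in the expression of single genes: 4 families had at least 1 mitochondrial gene 20-fold higher and 1 20-fold lower in the same pair, but that count restates the pattern. The test on cytosolic ribosomal protein genes decides nothing, since 0 families had at least 3 of 61 genes apart by a log2 of 2, where the share of all genes would give 1.26 to 2.37. Both explanations stay open.

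In Carolina Wren, the libraries labelled female 1 and male 3 had CHD1W at 8.29 and 63.8 CPM, each far from the 5 others with its label. Over 5 female-limited genes, 9 of 10 values lay within the range of the other sex's libraries. Z-linked genes had a median log2 difference of 0.426 in the library labelled female 1 and -0.421 in that labelled male 3 from birds of the same label, where the other 10 libraries lay between -0.16 and 0.21. Mixed RNA is argued against, since 1 of 10 values lay between the ranges of the sexes. An exchange of the libraries or of their labels may account for these values, no biological explanation was tested, and the labels were kept.

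Oxidative phosphorylation genes passed as higher in obligate nesters over the species means by camera with the preset correlation (median log2 0.14, adjusted p = 0.0437). They did not pass with an estimated one (adjusted p = 0.986), so that the call may reflect genes that vary together. The estimated correlation passed 0 of the 132 tests and was not checked on simulated lists, so it cannot decide this. Libraries that stand apart are argued against as the source of the value with the preset correlation, as the adjusted p without the 6 doubted libraries was 0.0152 with a median of 0.139. Whether the Passeridae pair alone carries it cannot be told apart: without it the median was 0.105 and 65.9% of the genes lay above 0, between the bounds set beforehand. The unadjusted camera p without Passeridae was 0.0360. By family the median was 0.36 in Passeridae, 0.20 in Hirundinidae, 0.14 in Turdidae, 0.02 in Troglodytidae and -0.03 in Parulidae. Without Parulidae, where 4 of the genes were higher and 11 lower, the median was 0.189 and 87.8% lay above 0. A link to nesting strategy stays open, and 2 of the other within-family assignments gave a smaller p for the list (1.29e-05 against 0.000331).

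Single birds far from the other birds of their species and sex were found in 11 of 79 tests, each of 1 group and 1 of 4 measures, where chance gives 3.95. Carolina Wren female 7 had a total of 7506324 counts (others 6143458 to 6638121). Fewer genes with counts than in the rest of the group were seen in Eastern Bluebird female 16 (10605), Eastern Bluebird male 12 (9739, others 10443 to 10631), American Robin female 2 (10589), House Sparrow female 3 (10605) and Prothonotary Warbler male 8 (10589). The mitochondrial share was 9.24% in Tree Swallow female 3 (others 6.29 to 7.19) and 19.8% in House Sparrow female 3 (others 8.74 to 12.9). CHD1W was at 10.6 CPM in Eastern Bluebird male 13 (others 0 to 0.325), and the other 2 cases are the CHD1W levels of the libraries labelled Carolina Wren female 1 and male 3.

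Tested differences between groups were the 6 genes whose sex difference depended on nesting strategy and the 9529 genes whose species difference varied among families.

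Other divisions of the same birds were tried for each count. For the families, 1 of 100 splits of the birds, the real one, gave as many genes in each family, and the highest other split gave 467 in Hirundinidae, 1 in Parulidae, 568 in Passeridae, 0 in Troglodytidae and 1 in Turdidae, so that chance division can be excluded. For sex, 1 of 25 splits gave as many genes (555, highest other 0), and chance division can be excluded there too. For lists by sex, 14 of 25 splits gave at least 4 lists (highest other 10), so that chance cannot be excluded for their number. In this permutation of the sexes within species the Z-linked list had p = 1.37e-130 by camera under the real labels and 1.09e-19 at the lowest in the other splits. That lowest camera p is below the 6.78e-16 of the Z genes with a W copy under the real labels. The p of the list of Z genes with a W copy was not kept for the other splits, so they do not give its own chance level.

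The other designs have too few assignments for a share under 0.05. Among 16 within-family assignments, 16 gave as many genes by strategy as the real 0 (highest other 0), which a real count of 0 fixes, 5 as many interaction genes as the real 6 (highest other 6), 6 as many lists as the real 2 (highest other 2), 15 as many concordant genes as the real 54 (highest other 78) and 10 as high a mean rho as -0.00105 (highest other 0.00455). All 10 splits of the families gave as many genes for the type of partner as the real 0 (highest other 0), which is fixed in the same way.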

How the results depend on the processing

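The fits without doubted libraries, without mitochondrial or sex-differing genes, and on the birds of the block without the block were chosen after the results were seen. In all, 47 counts moved by over 1.5 times. Requiring a 2-fold change left 1542, 1258, 1306, 1236 and 1892 genes in Hirundinidae, Parulidae, Passeridae, Troglodytidae and Turdidae, by construction. In Turdidae, males alone gave 3627 genes, and bird number as a block, which few birds share there, gave 1882. Other scalings, filters and tools kept the family counts within 1.5 times, and 190 values of named genes with RLE factors and 189 with DESeq2, which gave none for CISD1 in Passeridae, kept their direction and their side of the threshold.

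The 54 concordant genes became 26 in females alone (other assignments 23 to 38) and 22 in males alone (18 to 36), where fewer birds were fitted. They became 158 to 181 with a family left out and 332 in at least 4 of 5 families, which asks for fewer calls, and 17 with a log2 of at least 0.5 in every family. DESeq2 gave 61, RLE factors 56, and the fit without doubted libraries 56. The 0 genes by strategy became 5119 with birds as replicates in edgeR, and 320 with species as a random effect in voom, which take birds as units. They became 6 by phylogenetic least squares on the same species means. That fit has no family block and so another error, with the same log2 differences (-1.25 for CLCC1 in both). Leaving out Troglodytidae gave 3 genes for the type of partner, with 1 family left in 1 arm, and the cause was not tested.

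The 6 interaction genes became 11 without doubted libraries (4 shared), 11 without the libraries labelled Carolina Wren female 1 and male 3 (5 shared), 10 with DESeq2, 0 with limma on species differences, 1 with bird number as a block and 2 on the same birds unpaired. With a species left out they numbered 1 to 9, namely 1 without Tree Swallow, 3 without Yellow Warbler, Eurasian Tree Sparrow or House Sparrow and 2 without House Wren. Hirundinidae alone gave 10, Parulidae 11 and Passeridae 11. The cause was not tested. Expression gave no sign that bird numbers pair birds: of 40 pairs of a female and a male with 1 number, 15 correlated above 0.1 and the median was 0.02. Birds paired in the field need not correlate in expression, so these values cannot settle it.

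The 555 genes by sex stayed between 444 and 596 under other tools, scalings and libraries. In single species, with fewer birds, they were 352 in Tree Swallow, 228 in Barn Swallow, 290 in Prothonotary Warbler, 283 in Yellow Warbler, 290 in Eurasian Tree Sparrow, 190 in House Sparrow, 193 in Eastern Bluebird and 211 in American Robin. Carolina Wren gave 0, and 250 without the 2 libraries named above. With an estimated correlation, lists by strategy fell from 2 to 0 and lists by sex from 4 to 2, and fry, which asks another question, gave 40 by strategy. The species means limit the strategy comparison, with a median SE of 0.24 on the log2 scale.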

Other observations

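The count of mitochondrial genes in single libraries was chosen after the values were seen. In the library labelled House Sparrow female 3, COX3 was at 78272 CPM (3.90 to 20.3 in the other 11 House Sparrows), COX2 at 57581 CPM (172 to 446), ND1 at 30022 CPM (0 to 0.572), ND3 at 6248 CPM and ND5 at 10539 CPM. In that library ND2 was at 2.86 CPM (21953 to 49710 in the others) and ND4L at 0.659 CPM. All 121 libraries correlated best with the mean of their own labelled species, and this one had the smallest margin, with 0.892 for House Sparrow and 0.863 for Eurasian Tree Sparrow. On the TMM-scaled log2 scale, at least 1 mitochondrial gene lay 20-fold or more from the median of the other birds of the species in 10 libraries.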
